A study of Mus musculus with 10 samples.

How the data were processed

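The data were RNA sequencing libraries of pancreatic islets from 18-week-old C57BL/6 mice, 5 labelled floxed controls and 5 labelled knockouts. Per the labels, the knockout animals carried the tamoxifen-inducible Cre driver Pdx1-CreER together with floxed Grk5 alleles, and the controls carried the floxed alleles alone. Per the labels' protocols, islet RNA was depleted of ribosomal RNA, converted with a stranded random-primed kit, and sequenced on a NextSeq 500. The submitters' processing notes name STAR 2.4.0.1, HTSeq and DESeq2, without saying which step each served. The genome build, the annotation and the sex of the animals were not given in the sources used here.

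The deposited values were normalized counts per gene, a signal unit on a common scale between libraries, and they are not whole reads. Division of whole reads by 1 factor per library would leave whole multiples of 1 value, which most values were not. How they were made is therefore not known here. The authors' table held 17946 rows, of which 1 had no gene name and was left out (0.00774% to 0.0251% of a library's total). Another 23 names looked like dates, as spreadsheets make them from gene symbols. The same deposited table carried the authors' own comparison: log2 fold changes with standard errors, a test score per gene, and p-values with their adjusted values. These are quoted only where the authors' deposited table is named.

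The scale of the values limited the choice of test. Between 25.0% and 37.0% of the values above 0 in a library were whole multiples of that library's commonest low value, within a tolerance of 0.01 of a multiple. Whole reads could therefore not be recovered for most genes, and a count model, planned before the data were examined, was replaced by limma. In controls 2, 3 and 5, between 10.2% and 11.9% of the values lay midway between multiples, against 1.20% to 1.44% in the other 7 libraries. Whether these 3 were sequenced or processed differently is not given in the sources used here. They are all controls, so knockouts could not be compared with controls among them. If the commonest low value stands for 1 read, the library totals correspond to 2073111 to 10952860 reads. Midway values arise where the commonest low value stands for 2 reads. The totals estimated for controls 2, 3 and 5 may therefore be too low. Normalized totals ran from 5535773 to 7359001.

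Genes were kept with a normalized count of at least 10 in at least 5 libraries, which left 11711. Values were taken as log2(value + 8), and the groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, robust variance estimates and Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2(value + 8) scale, which understates the change of low genes. No pairing was used, because the labels give no replicate numbers. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries.

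Before the data were examined, 31 gene lists were fixed, and 29 had at least 3 members tested. They were compared with limma's camera at a preset correlation of 0.01 between genes. Each list was also tested with an estimated correlation, with the rotation test fry, and with an exact 2-sided permutation test of its mean log2 value per library. Genes are named by a rule fixed at the same time: Grk5, 19 other genes set in advance, the 10 with the smallest p in each direction where fewer than 5 passed, and up to 2 members of each list. Not every gene that this rule allows is reported here. The 10 per direction needed an official symbol and a mean CPM of at least 1 in a group. Dusp1, Esr1, 1700021K19Rik, Tmem38b, Zfp101, 0610011F06Rik and the genes that follow them, and any gene named for passing in a single alternative, were named after their values were seen.

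The alternatives were other scalings, filters, pseudocounts of 1 and 32, variance estimates, library quality weights, an acinar covariate and the omission of libraries. The limma steps were tested on simulated data made from the means and spread of these libraries, over 11320 genes. Of 97 genes changed 2-fold, 7.22% passed, and of 89 genes changed 4-fold, 46.1% passed. Both shares were higher among genes with mean values over 500, 25.0% and 100% of 16 genes each, while 6 unchanged genes were called. A list like the immediate early genes shifted by -0.6 on the log2 scale passed in 20 of 20 simulations, and 2 of 504 unchanged lists passed. The simulated genes varied independently, so these list results do not cover correlation between genes.

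Gene positions are from GENCODE M21 on GRCm38, which may not be the build the authors used. Of 17944 distinct symbols, 98.5% matched it by symbol or synonym. Correlations across libraries and figures were made in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.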

Results

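Islet RNA was profiled in 10 libraries from 18-week-old mice, 5 labelled control and 5 labelled knockout for Grk5 in β cells, the insulin-producing cells of the islet. Control and knockout below mean the libraries so labelled. Grk5 encodes a kinase that phosphorylates activated G protein-coupled receptors, and the series title ties it to β-cell proliferation through the class IIa histone deacetylase HDAC5. Knockout 3 held about 10952860 reads by the estimate from its low values, with 14632 genes above 0. Whether it was the deepest is open. Control 3, at 8299302 by the same estimate, would be deeper if its commonest low value stands for more than 1 read. The shallowest, knockout 1, held about 2073111 with 10222 genes above 0, and had the lowest median correlation with the other libraries, 0.718. No pair of libraries held identical values. Ins1 and Ins2 together took 12.3% to 17.8% of each library.

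The first comparison was of the targeted gene itself, which checks the labels. Grk5 lies on chromosome 19 from 60889749 to 61095968 on the plus strand in GRCm38. Its normalized counts were 197.0, 165.0, 386.9, 331.8 and 127.9 in controls 1 to 5, and 269.8, 129.9, 94.4, 207.0 and 105.5 in knockouts 1 to 5. The means were 242 ± 112 (SD, n = 5) and 161 ± 74.9 (SD, n = 5). The log2 fold change was -0.55 ± 0.42 (SE), with an adjusted p of 0.955 by limma, and 95% limits of -1.44 to 0.34. Without control 3 it was -0.36. An exact 2-sided permutation test gave p = 0.222, where the smallest p that 252 arrangements allow is 0.00794. Grk5 therefore did not separate the groups: knockouts 1 and 4 lay above controls 1, 2 and 5, and knockout 2 lay above control 5. These are whole-gene values from whole islets, in which any cells where the driver did not act would keep the gene. Which cells lost it was not measured, and the deleted exons were not analysed here. The authors' deposited table gives a log2 fold change of -0.60 with an adjusted p of 0.953.

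Esr1, which encodes the estrogen receptor α whose ligand-binding domain is part of CreER fusion proteins, was examined after its values were seen. It was between 1516.7 and 3176.8 in the 5 knockouts. Among the controls it was 2.0, 10.5 and 0.0 in controls 1, 3 and 4, but 2495.0 in control 2 and 773.5 in control 5. Over all 10 libraries its log2 fold change was 4.93 ± 1.71 (SE), with an adjusted p of 0.942 by limma. Leaving out controls 2 and 5 was an alternative chosen from these Esr1 values, so it gives no test of Esr1. Grk5 was then -0.94 ± 0.47 (SE) by limma, with an unadjusted p of 0.0619 and an adjusted p of 0.998. Over all libraries its unadjusted p by limma was 0.210. Across its alternatives the adjusted p ran from 0.877 to 0.999.

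**Figure D1:**
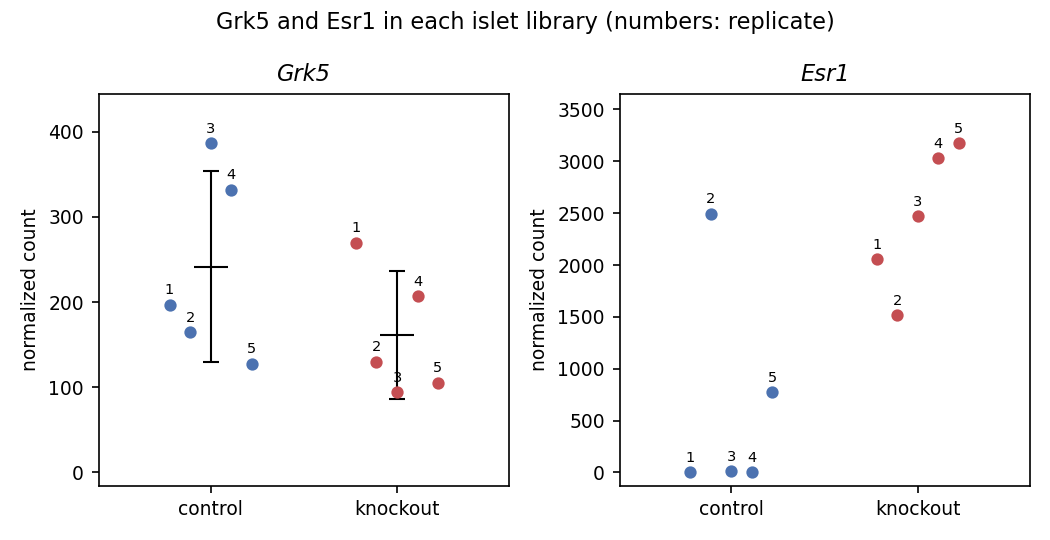
Normalized counts of Grk5 and Esr1 in each library, by labelled group; points are libraries with their replicate number, and for Grk5 the bars are the mean ± SD (n = 5). Grk5 overlaps between the groups, while Esr1 is at 1516.7 or above in every knockout and also high in control 2 (2495.0) and control 5 (773.5).

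The second comparison asked which genes differ in islets between the groups. Among genes with official symbols, the lowest p-values of those lower in the knockouts belonged to Commd8, the phosphatase gene Dusp5, the chromatin remodeller Smarcad1, Arid5a, the pyruvate dehydrogenase subunit gene Dlat and the ubiquitin ligase gene Ube3a. Those of genes higher in the knockouts belonged to Ppp4r1l-ps, Bend5, the autophagy gene Becn1, Ptges3l, the chromatin remodeller Smarca2 and the proteasome subunit gene Psmd13. The gene 1700021K19Rik, annotated as protein-coding but listed under a provisional symbol, was chosen after its values were seen. It was also higher, at a log2 fold change of 1.97 ± 0.44 (SE, unadjusted p = 0.000251 by limma). None passed the adjusted threshold. Of 11711 genes tested, 0 had an adjusted p under 0.05 by limma, and the smallest was 0.243, for Commd8. At an unadjusted p under 0.05 there were 276 genes higher and 311 lower, 587 in all, where 586 would be reached by chance. The groups did not overlap for 101 genes, 0.862% of those tested, where chance gives 0.794%. The authors' deposited table calls 19 genes at an adjusted p under 0.05, 13 higher and 6 lower, of which 10 were above 0 in 5 or fewer libraries. The 10 of them that were tested here all had an unadjusted p under 0.05 by limma. The authors' calls come from these same libraries, so this overlap is no independent evidence.

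Dusp5 on chromosome 19 (53529109 to 53542431) had 1115 ± 164 normalized counts in controls and 557 ± 105 in knockouts (SD, n = 5 each), a log2 fold change of -0.999 ± 0.22 (SE, adjusted p = 0.735 by limma). All 5 knockouts lay below the lowest control, and the authors' deposited table gives -0.998 with an adjusted p of 0.00453. Arid5a was 645 ± 103 against 308 ± 87.3, Dlat 312 ± 120 against 103 ± 36.8 and Ube3a 576 ± 121 against 229 ± 120. Commd8 was listed at 30.2, 118.8, 102.0, 71.7 and 171.7 in controls 1 to 5 and at 0 in all 5 knockouts. Npy, encoding neuropeptide Y, was listed at 21.6, 101.4, 11.5, 22.1 and 70.5 in the controls and at 0 in the knockouts except knockout 4 (2.4). Smarcad1, Thoc6, Isca2 and Fam189a1 had log2 fold changes of -3.14, -2.58, -2.35 and -2.50, each with knockout libraries listed at 0. Among genes with higher values, Ppp4r1l-ps, an annotated pseudogene on chromosome 2 (173579320 to 173659640), was 208 ± 134 against 734 ± 226, a log2 fold change of 1.91 ± 0.36 (SE, adjusted p = 0.293 by limma). It is the only gene past the adjusted threshold without control 1, at 2.22 ± 0.33 (SE, adjusted p = 0.0420 by limma, the lowest in a range up to 0.999 over its alternatives). Reads of a pseudogene may be shared with its parent gene, so its level is uncertain. Smarca2 was 1246 ± 236 against 1987 ± 218 and Nav2 1834 ± 305 against 2772 ± 363. Becn1, Psmd13 and Ccng1 had log2 fold changes of 1.25, 1.68 and 1.14. Bend5, Ptges3l and Hlcs, with control means of 35.0, 11.8 and 21.4, were at 2.48, 2.48 and 3.00. Bend5 was 95.2 in control 2, against 96.8 in knockout 3. Hlcs was 106.8 in control 4, above knockouts 2, 3 and 5 (68.2, 53.9 and 82.9).

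Of 29 gene lists, 2 passed by camera with a preset correlation, the immediate early genes and the acinar markers, both with lower values in the knockouts. Neither passed with an estimated correlation (adjusted p = 0.483 and adjusted p = 0.646). The immediate early genes, transcription factors and phosphatases switched on within minutes by calcium, growth factors or stress, had 29 of 34 members lower and 5 higher, with a median log2 fold change of -0.59. Nr4a1 was 1701 ± 459 in controls and 989 ± 326 in knockouts, Junb 1568 ± 389 against 917 ± 336, Fosb 6408 ± 1901 against 4152 ± 1110, and Arc 648 ± 289 against 311 ± 131 (SD, n = 5 each). Srf, the transcription factor that drives many of the others, was 1057 ± 175 against 685 ± 59.5, with every knockout below the lowest control. Egr1 was 3291 ± 1052 against 2152 ± 912 and Fos 2824 ± 1313 against 1710 ± 509, a log2 fold change of -0.57 that was -1.01 without control 2 and -0.37 without control 3. Dusp1 had a log2 fold change of -1.14 ± 0.39 (SE). Fosl1 was at -0.99 ± 0.89 (SE), and ran from -1.66 without control 2 to -0.56 without control 4. At an unadjusted p under 0.05 there were 8 members lower and 0 higher. No member passed over all genes, and 1, Dusp5, passed when adjusted over the list alone.

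Camera with a preset correlation gave the immediate early genes an adjusted p of 1.79e-08 over the 29 lists, and an adjusted p = 0.483 with an estimated correlation. The mean log2 value per library was 8.67 ± 0.36 in controls and 8.14 ± 0.33 in knockouts (SD, n = 5 each), for which an exact permutation test gave p = 0.0476 and an adjusted p = 0.756. Fry gave an adjusted p of 0.219. The mean of the acinar markers per library differed by -0.91, knockout minus control, with an exact permutation p = 0.183.

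Of 26 acinar markers, transcripts of the digestive enzyme-secreting cells that surround islets, 25 were lower in the knockouts and 1 higher, with a median log2 fold change of -0.94. Try5, a trypsinogen gene, was 6416 ± 3119 against 2097 ± 922, and the carboxypeptidase gene Cpb1 was 7094 ± 5015 against 2759 ± 970 (SD, n = 5 each). The list's adjusted p by camera was 8.20e-11 with the preset correlation, and the adjusted p = 0.646 with an estimated correlation. The list's mean log2 value was 10.6 ± 1.30 in controls and 9.64 ± 0.56 in knockouts (SD, n = 5 each, exact permutation p = 0.183, adjusted p = 0.756). Control 2 (8.51) lay below every knockout (9.04 to 10.5), and control 4 (12.1) was the highest of the 10 libraries. The list's adjusted p by camera was 1.52e-35 without control 2 and 4.69e-05 without control 4. At an unadjusted p under 0.05, 1 member was lower, and 0 passed when adjusted over the list alone.

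**Figure D2:**
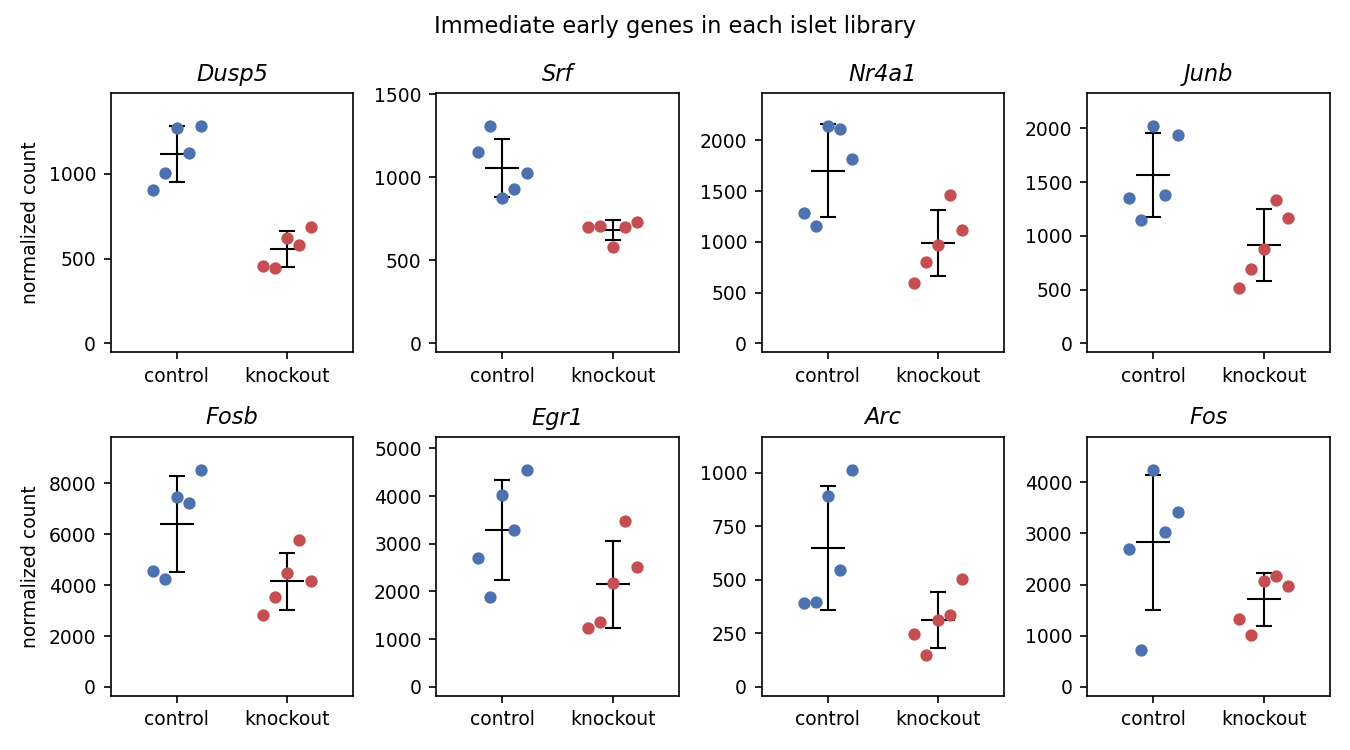
Normalized counts of 8 immediate early genes in each library, by labelled group; points are libraries and bars are the mean ± SD (n = 5). The groups do not overlap for Dusp5 and Srf, and overlap for the other 6 genes.

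None of the β-cell and hormone genes passed the adjusted threshold. Ins2 was at a log2 fold change of -0.01 ± 0.10 (SE) and Ins1 at -0.08 ± 0.06, with 95% limits of -0.21 to 0.05 for Ins1. Glucagon (Gcg) was at -0.12, somatostatin (Sst) at -0.13 and pancreatic polypeptide (Ppy) at -0.46 ± 0.36. With single libraries left out, Ins2 ran from -0.10 (knockout 5) to 0.03 (control 4), Ins1 from -0.13 (knockout 5) to -0.04 (knockout 3), Gcg from -0.19 (knockout 4) to -0.04 (knockout 2), Sst from -0.17 (knockout 5) to -0.06 (control 2) and Ppy from -0.76 (knockout 4) to -0.24 (knockout 1). The direction of Ins2 also turns with total-count scaling, and that of Gcg and Sst without controls 2 and 5. Among 23 β-cell identity genes, 18 were lower and 5 higher, with a median of -0.21 and an adjusted p of 0.0622 by camera (adjusted p = 0.483 with an estimated correlation). The glucose transporter gene Slc2a2 was 2923 ± 299 against 2120 ± 514, and Pdx1, Mafa and Glp1r had log2 fold changes of -0.25, -0.34 and -0.29. Pdx1 ran from -0.38 without knockout 5 to -0.12 without knockout 1, and Mafa was -0.21 without control 1. The β-cell identity list's adjusted p was 0.0178 without controls 2 and 5, 0.0108 without control 2, 0.0155 without knockout 5 and 0.0461 without knockout 1, in a range of 0.0108 to 0.895 over its alternatives. Over all libraries it passed by camera with upper-quartile scaling (adjusted p = 0.0354) and quality weights (0.0140). By camera it also passed with a minimum normalized count of 50 (0.0360) and a pseudocount of 32 (0.0455), but not with total counts (0.151). Of 22 genes of insulin processing and exocytosis, 16 were higher and 6 lower (median 0.09, adjusted p = 0.271), with Scg2 at 0.30 ± 0.10 and Snap25 at 0.52 ± 0.24, or 0.33 without control 4. The alpha cell markers (9 tested, median -0.16) and the delta and PP cell markers (6 tested, median -0.14) had adjusted p of 0.996 and 0.634. Gc, which encodes a vitamin D-binding protein made by alpha cells, was 346 ± 82.1 against 733 ± 202 and passed when adjusted over the alpha list alone. Of 7 disallowed and progenitor genes, 4 were higher (median 0.24, adjusted p = 0.726), with Aldh1a3 at 1.95 ± 0.76.

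The genes of the proposed GRK5 and HDAC5 route and of proliferation did not pass either. Hdac5 was 823 ± 312 in controls and 745 ± 206 in knockouts, a log2 fold change of -0.11 ± 0.27 whose direction turns without control 5 (0.08) and without controls 2 and 5 (0.015), and which was -0.26 without knockout 2. In the class IIa HDAC and MEF2 list (6 tested, adjusted p = 0.961), Hdac7 was at 1.28 ± 0.71, and at 0.59 without control 5, where it was listed at 0. Mef2d was at -0.18 ± 0.25, and from -0.35 without knockout 5 to -0.02 without knockout 1. The other GRK and arrestin genes (7 tested with Grk5) had a median of -0.05 and an adjusted p of 0.996. Mki67, the proliferation marker, was 159.6, 180.9, 11.5, 181.1 and 0.0 in controls 1 to 5 and 578.6, 159.3, 139.2, 178.8 and 11.6 in knockouts 1 to 5. Of 40 genes in the S phase and mitosis list, 22 were tested, and the values cover only those. Of these 22, 14 were higher, with a median of 0.34, an adjusted p of 0.634 and Mcm4 at -1.59 ± 0.71. Ccnd2 was at -0.03 ± 0.12, and Ccnd1 at -0.00 ± 0.30, with directions that turn under other scalings and with single libraries left out, where Ccnd1 ran from -0.27 (knockout 1) to 0.16 (knockout 3). The cell cycle inhibitor gene Cdkn1a was at 0.68 ± 0.41 and Cdk6 at -1.69 ± 0.65. The G1 cyclin and inhibitor list (11 tested) had 9 members lower, a median of -0.37 and an adjusted p of 0.634.

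Among the stress and metabolic lists, cholesterol and fatty acid synthesis had 19 of 22 members lower (median -0.27, adjusted p = 0.0550 by camera). Acaca, which makes malonyl-CoA for fatty acids, was 345 ± 200 against 658 ± 340. The cholesterol and fatty acid synthesis list's adjusted p was 0.0214 without controls 2 and 5, and with single libraries left out the list's adjusted p was 0.0135 without control 4, 0.0201 without knockout 4, 0.0353 without control 5, 0.0400 without control 2 and 0.050 without knockout 2. Over all libraries it passed by camera with upper-quartile scaling (adjusted p = 0.0354), no filter on low values (0.0239) and quality weights (0.0221). By camera it also passed with a minimum normalized count of 50 (0.0360), the acinar covariate (0.0413) and a pseudocount of 32 (0.0359). With total counts it did not (adjusted p = 0.0780 by camera). The list's range over its alternatives was 0.0135 to 0.756, with an adjusted p = 0.483 with an estimated correlation over all libraries. The heat shock genes had 8 of 11 lower (median -0.22, adjusted p = 0.0782 by camera, adjusted p = 0.744 with an estimated correlation), and Dnaja1 and Hspa8 passed when adjusted over the list alone, at -0.53 ± 0.16 and -0.36 ± 0.12. The list's adjusted p was 0.00451 without knockout 5, 0.00926 without control 4, 0.0199 without knockout 3, 0.0452 without control 3 and 0.0188 with a minimum normalized count of 50, in a range of 0.00451 to 0.921 over its alternatives. The unfolded protein response had 17 of 22 lower (median -0.07, adjusted p = 0.381, and adjusted p = 0.857 with an estimated correlation). This list's adjusted p was 0.0482 without control 3, in a range of 0.0482 to 0.922 over its alternatives. Hspa5 was at -0.19 ± 0.10, or -0.09 without control 1, and Chac1 at -0.59 ± 0.32, or -0.35 without knockout 1. The cAMP and CREB targets (12 tested, adjusted p = 0.509), NF-kB and inflammatory genes (15 tested, 0.634) and interferon response (16 tested, 0.822) had medians of -0.17, -0.13 and -0.10. The inflammatory chemokine gene Cxcl10 was at -1.93 ± 0.72, and Cish, a target of lactogen signalling, at -1.43 ± 0.55. The lactogen response list (8 tested) had an adjusted p of 0.970. Glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins and circadian clock genes had medians of 0.06, 0.01, -0.05, 0.02 and -0.01, with adjusted p of 0.962, 0.970, 0.996, 0.961 and 0.726.

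Of the other cell types an islet preparation can hold, none but the acinar list passed by camera with the preset correlation, and that list had an adjusted p = 0.646 with an estimated correlation. The ductal (8 tested, Krt7 at 0.54 ± 0.26 and 0.34 without knockout 5), endothelial (14 tested, Kdr at 0.37 ± 0.22), macrophage (10 tested) and fibroblast and pericyte (8 tested) lists had medians of 0.13, 0.09, 0.02 and 0.01, with adjusted p of 0.961, 0.822, 0.961 and 0.996. The Schwann and neural (3 tested) and erythroid (4 tested) lists had medians of 0.29 and -0.19, with adjusted p of 0.726 and 0.961. The lymphoid and adipocyte lists had 2 and 1 members tested and were left out. The direction by camera differed in sign from the median or the mean in 10 lists that did not pass, those of the circadian clock, endothelial, class IIa HDAC, fibroblast, mitochondrially encoded, GRK, alpha, ribosomal, lactogen and nuclear oxidative phosphorylation genes. With 5 libraries per group and a median standard error of 0.56 on the log2 scale, changes of single genes near 2-fold were mostly not detectable.

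**Figure D3:**
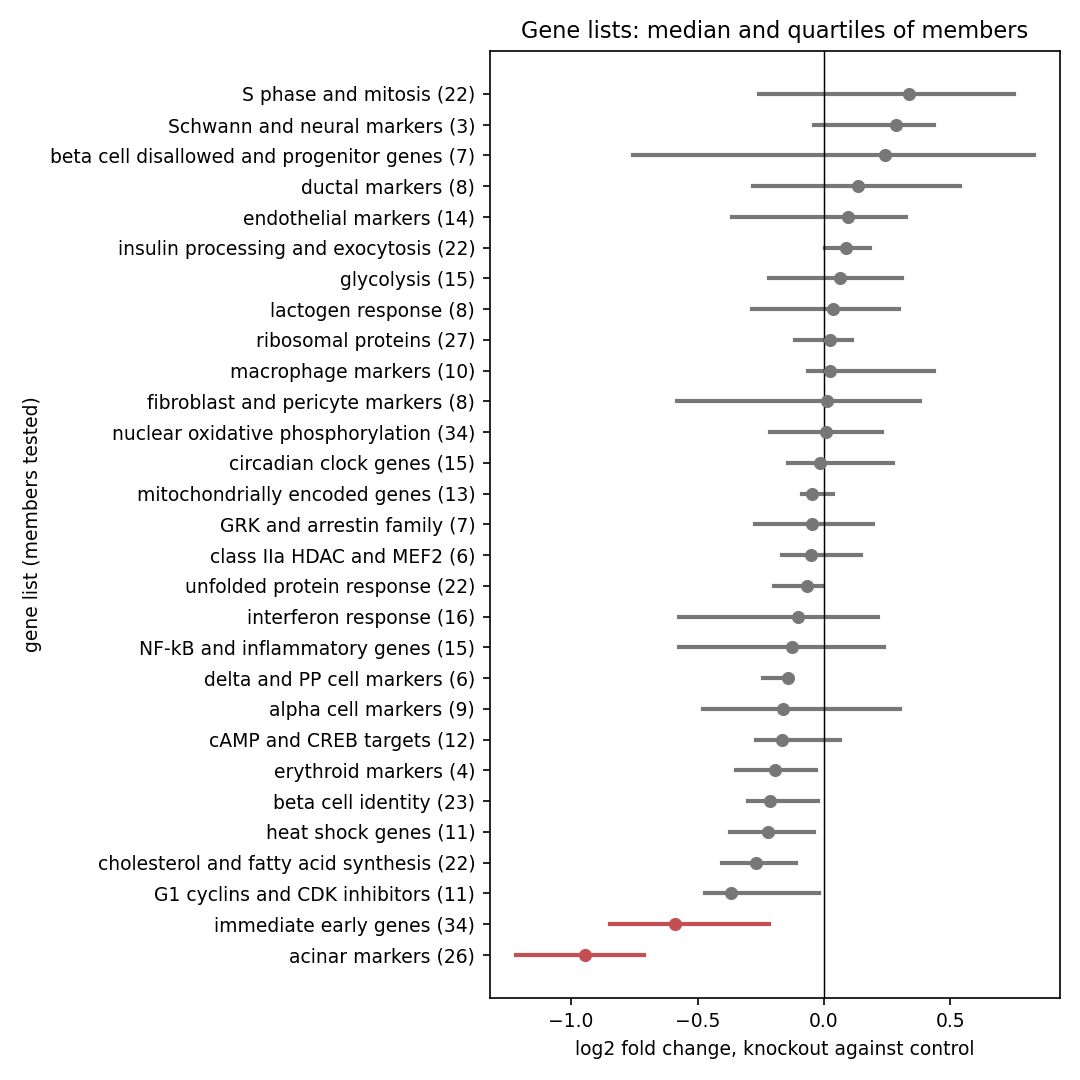
Median log2 fold change of the tested members of 29 gene lists, knockout against control (points), with the quartiles of the members (lines); the number of members tested is in brackets. The 2 lists in red, acinar markers (median -0.94) and immediate early genes (median -0.59), passed an adjusted p of 0.05 by camera with a preset correlation and did not with an estimated one.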

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

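All tests in this part other than the counts of other splits of the libraries and the test of depth were chosen after the results were seen. In groups of 5 libraries, a value was singled out when its gap to the nearest other, over the group's range, exceeded 0.71. Of 196 groups examined 19 did, 9.69%. A chance rate of about 1 in 20 groups, or 9.8, holds only for normally distributed values. Single genes were examined as normalized counts, and some had been chosen for small p-values, so that rate is no baseline here. The 19 groups are therefore listed as a description, and no excess over chance is drawn from them.

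Among the lists, the erythroid mean in the knockouts had a ratio of 0.793 (knockout 4 highest, 6.30 on the log2 scale) and the ribosomal protein mean 0.719 (knockout 5 highest, 11 on that scale). Among hormone genes, Ins2 in the knockouts had 0.948 (knockout 5 highest) and Ppy in the knockouts 0.749 (knockout 4 highest). For genes lower in the knockouts, the ratios in that group were 0.779 for Srf (knockout 3 lowest, 580.6), 0.724 for Dlat (knockout 1 highest), 0.901 for Thoc6 (knockout 2 highest), 1 for Npy (knockout 4, 2.4, with the others at 0), 1 for Isca2 (knockout 3 highest) and 0.750 for Cxcl10 (knockout 5 highest). Psmd13, Ccnd1 and Hspa5 in the knockouts had 0.783 (knockout 1 highest), 0.732 (knockout 1 highest) and 0.711 (knockout 4 lowest). In the controls, the ratios were 0.801 for Isca2 (control 4 highest), 0.749 for Ppp4r1l-ps (control 1 highest), 0.764 for Bend5 (control 2 highest), 1 for Hlcs (control 4 highest, the others at 0), 0.732 for Gc (control 2 lowest) and 0.730 for Hdac5 (control 5 highest, 1357.1).

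The number of genes at an unadjusted p under 0.05, 587, could be reached by chance: 20 of 100 splits of the 10 libraries into groups of 5 gave as many, and the highest of the others gave 671. At the adjusted threshold, where the real split gave 0 genes, 16 of the 100 splits gave at least 1. Likewise 46 of 100 splits gave 2 or more lists past the threshold, with a highest other of 5, and 77 gave at least 1. For the acinar markers 19 of 100 splits gave a camera p as small, with the real -log10 p at 11.6 and the highest other at 54.2, so chance is not excluded for that list.

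The immediate early genes were lower in the knockouts by 0.53 ± 0.22 (SE) in the mean log2 value per library. For this list 4 of 100 splits gave a camera p as small, the real one included, and another split reached a -log10 p of 14.9 against the real 8.91. That share is for this list taken alone; it was 1 of 29 tested, 77 of 100 splits gave at least 1 list past the threshold, and its exact permutation test had an adjusted p of 0.756, so chance is not excluded. RNA from acinar cells may contribute, although the acinar mean did not separate the groups (exact permutation p = 0.183): with it as a covariate the difference was -0.371 ± 0.226 (SE), with 95% limits of -0.904 to 0.163, against -1.03 to -0.0274 without a covariate. Handling stress that also moves heat shock genes stays open too: with their mean, which differed by -0.0527 between the groups (exact permutation p = 0.683), as a covariate the difference was -0.495 ± 0.216 (SE), with 95% limits of -1.01 to 0.0161. The heat shock mean holds Hsph1, at a log2 fold change of 1.75 ± 1.14 (SE). Of the 11 members, 8 were lower, with a median of -0.22. That mean is therefore a weak measure of handling stress. Neither covariate decides with 10 libraries, and loss of Grk5, or the Cre driver that the labels give to the knockout genotype alone, remains untested among the open explanations.

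Esr1 was high in the 5 knockouts and in controls 2 and 5, and at most 10.5 in controls 1, 3 and 4. Reads of the CreER transgene's receptor domain, assigned to Esr1, could give the values of the knockouts, but with every label right they cannot give those of the controls: 2 control libraries reached at least 0.1 of the lowest knockout. Controls 2 and 5 are also among the 3 controls with many values midway between multiples of the low value, but control 3, which shares that, was at 10.5. A wrong label, or controls that carried the driver, may account for that, but Grk5 does not decide it: its values in controls 2 and 5 reached at most 165.0, within the knockout range, yet control 1 (197.0) also lies below knockout 1 (269.8). Failed estimates listed near 0 in controls 1, 3 and 4 stay possible, as 20 other genes were under 15 in exactly 3 libraries and at least 100 in the other 7, though 0 of them were low in those 3 controls. The groups were kept as labelled, and a change in the animals' own Esr1 was not tested.

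Tmem38b, Zfp101 and 0610011F06Rik took 5.86% (knockout 2) to 28.1% (knockout 1) of a library and varied together. Over 10 libraries Zfp101 followed Tmem38b with r = 0.980 (permutation p = 2e-05, the smallest the resampling can give) and rho = 0.927 (permutation p = 0.00028), and without the 2 farthest libraries r was 0.940; the adjusted p over 5 relations were 5e-05 and 0.0006. Small RNA genes inside host genes are a candidate source: of 19 other genes with r over 0.9 to Tmem38b, 68.4% hold an annotated small RNA gene on their strand in GENCODE M21, such as Rpl5, Eif4a2 and Rps20, against 12.6% of 3184 other genes with a mean over 300 (Fisher's exact p = 3.16e-08). Those 19 genes were picked for varying together, so they are not independent, and the Fisher p overstates the evidence. Ribosomal protein and translation genes are among them, such as Rpl10, Rpl12 and Eif4g2. Whether that class alone gives the higher share was not tested. Tmem38b itself holds a 5S ribosomal RNA gene (chromosome 4, 53860652 to 53860770), while Zfp101 and 0610011F06Rik hold none. Depth cannot be told apart as a source: the share had r = -0.488 with depth (permutation p = 0.15; rho = -0.479, permutation p = 0.16), which became 0.0974 without knockouts 1 and 3. The depth used there took the commonest low value as 1 read, which may make it too low for controls 2, 3 and 5. No biological explanation was tested for these features, whose log2 fold changes between groups were -0.17 for Tmem38b, -0.07 for Zfp101 and -0.06 for 0610011F06Rik.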

How the results depend on the processing

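Pseudocounts, the minimum of 50, library quality weights, the exact test of list means and both sets of omitted controls were chosen after seeing the data. Genes past the adjusted threshold numbered 0 in 20 of 23 alternative fits, 3 without controls 2, 3 and 5 (Amy2a1, Esr1 and Herc4), 1 without controls 2 and 5 (Esr1), and from 0 to 1 with a single library left out (1 without control 1). Both omissions remove the controls high in Esr1, so neither tests it, and Herc4 is listed at 0 in controls 1 and 4, those left in the first. Lists past the threshold numbered 4 with upper-quartile scaling, quality weights, a pseudocount of 32 or without controls 2 and 5, 5 with the minimum of 50, and 0 with an estimated correlation, fry or exact tests. They numbered from 2 to 4 with a single library left out. The adjusted p of the immediate early genes was 0.483, 0.219 and 0.756 under those last 3 tests and that of the acinar markers 0.646, 0.625 and 0.756. The immediate early genes passed in 23 of 26 settings and the acinar markers in 22 of 25. Every setting in which they passed used camera with the preset correlation, so these tallies do not test that assumption. The estimated correlations between members were higher than the preset one, at 0.176 and 0.725. With single libraries left out, the adjusted p by camera with the preset correlation ran from 8.57e-12 to 2.38e-05 for the immediate early genes. For the acinar markers it ran from 1.52e-35 to 4.69e-05. Grk5 kept its direction throughout, from -0.76 without knockout 1 to -0.36 without control 3 with single libraries left out. Without controls 2 and 5 it was -0.94. With library quality weights over all libraries it was -0.94 ± 0.40 (SE, unadjusted p = 0.0277 and adjusted p = 0.877 by limma). These weights were chosen after seeing the data, so that unadjusted p is given as a description.

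Of 64 named genes, 7 turned direction in some setting; the cause was not tested. With total counts Ins2 was 0.012 and Ccnd1 0.017, without features over 1% of a library Ccnd1 was 0.038 and Ccnd2 0.0083, and with the acinar covariate Ins2 was 0.073 and Ccnd2 0.095. Without controls 2, 3 and 5, Hdac5 was 0.059, Gcg 0.077, Sst 0.0038, Mki67 -0.35 and Ccnd1 0.063. Without controls 2 and 5, Hdac5 was 0.015, Gcg 0.030, Sst 0.010 and Ccnd1 0.15. With single libraries left out, Ins2 ran from -0.096 to 0.034, Ccnd1 from -0.27 to 0.16, Ccnd2 from -0.11 to 0.0032 and Hdac5 from -0.26 to 0.083. The planned DESeq2, edgeR and voom fits were not run, because the values were already normalized by an unknown route and whole reads could not be recovered for most genes. The planned surrogate variable, from a method for counts, was left out, and none was estimated from the log2 values. The sex covariate was not run, because Xist is not among the symbols analysed here. Knockout 1, the shallowest library by the estimate, had the most genes at 0, 43.0%. That share did not follow depth throughout. Knockout 4, at 2716088 estimated reads, had 26.6% of genes at 0, and control 1, at 4712858, had 30.8%.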

Other observations

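Some genes are listed at 0 in part of the libraries and far above 0 in others. The authors' deposited table gives Commd8 a log2 fold change of -8.53 with an adjusted p of 2.96e-09, from 5 controls above 0 and 0 knockouts above 0. Of its 19 calls, 11 have a log2 fold change of over 6 in size, among them Glrx at 22.5 from 2 libraries above 0 and Fam133b at -22.7 from 2 libraries above 0. Herc4 was listed at 0 in controls 1 and 4, at 329.6, 231.7 and 142.3 in controls 2, 3 and 5, and at 197.6 to 642.7 in the knockouts.

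Over the 10 libraries the mean of the immediate early genes followed that of the acinar markers with r = 0.638 (permutation p = 0.048) and rho = 0.648 (permutation p = 0.049), the adjusted p over 5 relations being 0.06 and 0.0612. Without controls 2 and 4, the farthest in the acinar mean, r was 0.614. Both means were lower in the knockouts, and the groups were pooled here. The permutation did not account for group, so part of the relation may reflect the difference between groups.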
